A study of Homo sapiens with 6 samples.

How the data were processed

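RNA was sequenced from 6 libraries of the triple-negative breast cancer line MDA-MB-231, for siControl, siNCOA3 and siSHC1 collected 24 h and 48 h after transfection, with 1 library for each siRNA and time. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded mRNA kit from 1 µg of total RNA. Per the submitters' processing notes, STAR, Cufflinks and DESeq2 were used with the genome build hg19, with no roles or versions given. The annotation, the filters and whether strand was used in quantification are not given in the sources used here. The deposited table is named for read counts, but the values the authors deposited are FPKM (fragments per kilobase of gene and per M fragments): they are not whole, and among low values 1 fragment is worth less in longer genes. The table gives gene symbols only, for 20111 genes, and all 6 sample columns were used.

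The analysis had been planned for read counts. As FPKM are not counts, the planned count test was not used, and limma took its place with the same design. FPKM were scaled between libraries by the median of ratios to the geometric mean over 11042 genes, with factors between 0.947 and 1.02. Genes with at least 1 FPKM in at least 2 libraries (11690 genes) were tested on log2(scaled FPKM + 1), the pseudocount being 1, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust moderation). The model held additive terms for siRNA and time over all 6 libraries, which leaves 2 residual degrees of freedom. Its error holds library noise and any siRNA-by-time difference, so that a call asks for a like change at both times. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The comparisons were siNCOA3 with siControl, siSHC1 with siControl, siSHC1 with siNCOA3, and 48 h with 24 h. Fold changes between single libraries of one time have no replicate check and were given no p-value.

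The design, the gene lists, the rule for named genes and the alternatives were fixed beforehand, apart from those named as added later. The rule names NCOA3 and SHC1. For each comparison of an siRNA with siControl, and for time, it then names the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 FPKM (planned as CPM) and the same sign in every pair of libraries, and 5 in each direction for siSHC1 with siNCOA3. Where fewer than 5 passed in a direction, the genes with the largest smallest change over the pairs fill up to 5, as values with no call. From each list discussed it names up to 4 members with the largest change in the direction the list moved, or in size where it did not. Other called members of a list, and genes said to be picked later, stand outside the rule.

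The 28 gene lists hold 945 symbols, of which 940 were matched to the table, older symbols through a RefSeq table of synonyms. Lists were tested with camera (limma, preset correlation 0.01, and with an estimated correlation) and with fry, adjusted over the 28 lists. For single pairs of libraries, a list's median was placed among 10000 random lists of the same size matched on mean expression. The relative depth was estimated from the most frequent ratio between libraries among genes below 0.3 FPKM. Between 38.9% and 42.3% of these ratios fell on whole-fragment steps, within a tolerance of 0.02 on the log2 scale. This is too few to recover counts, so that no binomial interval or detection limit is given, and an exact 0 is only said to be listed at 0.

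Transcript sequences and 3′ UTRs came from GENCODE annotation of GRCh38, matched by symbol to 97.9% of the tested genes. As that build differs from the authors', only the chromosome of the targets is given. All 7-base words were tested for a relation between presence in the 3′ UTR (at least 30 bases) and the mean fold change, as a z over 11276 genes, beside 100 permutations of the fold changes within bins of 3′ UTR length. Whether the words belong to the siRNAs is not known, since the siRNA sequences are not given in the sources used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for this search and the plots.

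The test was tried on simulated libraries in which a set of genes was changed by known sizes. For siNCOA3 87.9% of genes changed by 0.585 on the log2 scale and 98.5% of those changed by 1 were recovered, with 28 false calls among 11596 genes. For siSHC1 these were 92.7% and 100%, with 19 false calls among 11603 genes, and for time 93.7% and 98.2%, with 26 among 11580. The genes changed by 0.585, 1 and 1.5 numbered 66, 67 and 67 for siNCOA3 and 55, 62 and 83 for siSHC1. For time they numbered 63, 55 and 82. Even with every changed gene called, the false calls would make up more of the calls than the adjusted p threshold allows. In these simulated libraries the threshold was therefore not held in any of these comparisons. The alternatives were no scaling, equal library totals, other filters and pseudocounts, no robust moderation, no term for time or siRNA, the libraries of the compared groups alone, and each library left out in turn. Where leaving out a library leaves an siRNA with 1 library, that library is assumed to vary like the others.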

Results

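Messenger RNA was sequenced from MDA-MB-231 cells, an established human line of triple-negative breast cancer, the form of the disease that lacks oestrogen receptor, progesterone receptor and amplified HER2. The cells had been transfected with a control siRNA (siControl), an siRNA against NCOA3 (siNCOA3) or an siRNA against SHC1 (siSHC1), and were collected 24 h or 48 h later. NCOA3 is a coactivator that binds nuclear receptors, and SHC1 is an adaptor protein that couples receptor tyrosine kinases to RAS. The series is titled for nuclear receptors and their coregulators in this cancer, and its design text states gene knockdown followed by RNA sequencing. Each of the 3 siRNAs has 1 library at each of 2 times, which makes 6 libraries, 2 per siRNA and 3 per time. No siRNA has a replicate at one time, so the 2 times serve as the replicates of an siRNA and the 3 siRNAs as the replicates of a time. The labels do not say whether the libraries came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical, together with any difference in response between the times.

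The values are FPKM for 20111 genes. Total FPKM per library ran from 495518 (siControl, 24 h) to 553073 (siSHC1, 24 h), and 14796 to 15221 genes had a value above 0. The steps between the lowest values put the depth, relative to siControl at 24 h, at 1.45 for siControl at 48 h, 1.20 and 1.31 for siNCOA3 at 24 h and 48 h, and 1.03 and 1.01 for siSHC1. These steps imply about 18.6 M fragments in the siControl library of 24 h and 27.2 M in that of 48 h, the deepest of the 6. Mitochondrially encoded transcripts held 17.3% to 18.7% of the FPKM of a library. After the filter on low values, 11690 genes were tested. A fold change is given on the log2 scale of scaled FPKM plus 1, with its standard error (SE), and understates the change of genes with low values.

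The targeted transcripts were examined first. NCOA3 (chromosome 20) fell from 10.3 to 1.72 FPKM at 24 h and from 11.4 to 1.85 FPKM at 48 h after siNCOA3, which left 15.4% and 16.3% of the siControl level after scaling. SHC1 (chromosome 1) fell from 103 to 14.7 FPKM at 24 h and from 119 to 15.5 FPKM at 48 h after siSHC1, which left 13.4% and 13.3%. In the fitted model NCOA3 fell by 2.13 ± 0.10 on the log2 scale after siNCOA3 (SE, n = 2 libraries per siRNA, limma adjusted p = 0.00122). SHC1 fell by 2.83 ± 0.08 after siSHC1 (limma adjusted p = 5.11e-05). NCOA3 stood at 12.7 and 12.5 FPKM after siSHC1, or 115% and 111% of siControl, and SHC1 stood at 109 and 107 FPKM after siNCOA3, or 98.0% and 90.8%. Both targets therefore matched the labels of all 6 libraries.

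**Figure D1:**
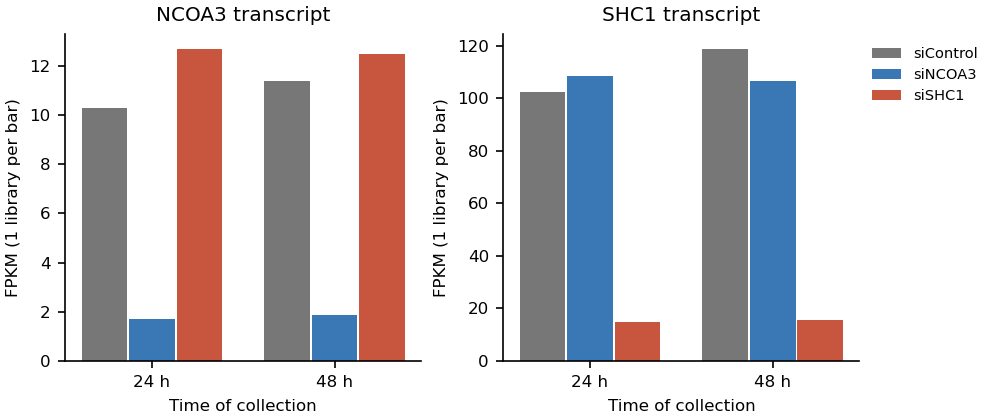
FPKM of NCOA3 (left) and SHC1 (right) in each library, 1 bar per library, grouped by time of collection and coloured by siRNA. NCOA3 stands at 1.72 and 1.85 FPKM in the siNCOA3 libraries and at 10.3 FPKM or more in the other libraries, and SHC1 stands at 14.7 and 15.5 FPKM in the siSHC1 libraries and at 103 FPKM or more in the others.

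The comparison of siNCOA3 with siControl asks which transcripts depend on NCOA3 in these cells. Besides NCOA3, the largest falls among genes with a mean of at least 5 FPKM were in RPN2, a subunit of the oligosaccharyltransferase of the endoplasmic reticulum, which went from 213 to 59.9 FPKM at 24 h and from 273 to 57.3 FPKM at 48 h, and in CBFB, the partner subunit of the RUNX transcription factors, which went from 35.6 to 11.3 and from 35.8 to 10.7 FPKM. RPN2 fell by 2.07 ± 0.09 on the log2 scale (SE, n = 2 libraries per siRNA, limma adjusted p = 0.00118) and CBFB fell by 1.66 ± 0.12 (limma adjusted p = 0.00663). NGFR, the low-affinity neurotrophin receptor, fell by 1.33 ± 0.15, F2RL1, a protease-activated receptor, fell by 1.13 ± 0.09, and RRBP1, a ribosome-binding protein of the endoplasmic reticulum, fell by 1.02 ± 0.07. CSF1, the macrophage growth factor, fell by 0.93 ± 0.10, FERMT2, an integrin-binding adaptor of focal adhesions, fell by 0.93 ± 0.10, FAM115A fell by 0.90 ± 0.09, and BCL2L1, which encodes the survival protein BCL-XL, fell by 0.90 ± 0.07.

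In all, 13 of 11690 genes changed after siNCOA3 (limma, Benjamini-Hochberg adjusted p under 0.05), and all 13 fell. They fell at both times, a like change that the fit asks of a call. In 20 simulated sets of unchanged libraries the test made up to 10 calls for siNCOA3, and up to 15 with depth noise added, so the number 13 by itself does not stand above what no change can give. The other 3 were PHLDA1, which fell by 0.77 ± 0.07, the RNA-binding protein PCBP1, which fell by 0.72 ± 0.07, and LSP1, which was listed at 0 in both siNCOA3 libraries and both siSHC1 libraries, against 7.37 and 5.08 FPKM in the siControl libraries. PCBP1 and LSP1 were picked out after their values were seen. By limma 0 genes rose, while 1226 genes had an unadjusted p under 0.05 in either direction, against 584 expected by chance. Among genes with a mean of at least 5 FPKM, chosen by their smaller rise of the 2 times, none passed the test, and the values were 2.04 ± 1.49 for AC012360.2, 1.71 ± 0.50 for CTC-429P9.4, 0.75 ± 0.14 for AMMECR1, 0.70 ± 0.11 for TBC1D24 and 0.64 ± 0.14 for TMCC1. A 2-fold change of the same sign at both times, counted without a test, was seen in 11 genes, 4 higher and 7 lower, and 3 genes changed 2-fold in opposite directions. The count of 13 became 3 when either the siControl or the siNCOA3 library of 48 h was left out, 8 without siControl at 24 h, 28 and 30 without the siSHC1 library of 24 h and 48 h, 7 without scaling and 0 without a filter on low values, where 1375 genes had an unadjusted p under 0.05 (limma). The 7-base word GTCAAGA, which occurs in the NCOA3 transcript outside its 3′ UTR, lies in the 3′ UTR of RPN2, CBFB, CSF1, FAM115A, PHLDA1 and PCBP1, that is in 6 of the 12 genes other than NCOA3 that fell, or 50%, against 8.04% of all genes with a 3′ UTR. It was chosen from all 7-base words by these same fold changes, so its share is favoured by that choice.

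Gene lists fixed before the data were examined were compared with all other tested genes by camera, with a preset correlation between genes of 0.01. After siNCOA3 the 55 cytoplasmic ribosomal protein genes were shifted up, with a median of 0.14 and 53 members above 0 (camera adjusted p = 3.85e-18, and adjusted p = 0.834 with an estimated correlation), and RPLP1 stood at 0.26, RPS10 at 0.23, RPSA at 0.23 and RPL24 at 0.23. The 25 measured genes of NF-kB and inflammatory cytokines were shifted down, with a median of -0.29 and 22 members below 0 (camera adjusted p = 4.50e-06). CSF1 was the member called among all genes, 3 members fell when adjusted over the list alone, and CSF2 at -0.88, NFKBIZ at -0.65 and IL6 at -0.48 did not pass over all genes. The 40 nuclear-encoded genes of oxidative phosphorylation were shifted up, with a median of 0.089 and 33 above 0 (camera adjusted p = 1.70e-04), with ATP5G1 at 0.27 and UQCRH at 0.25. The 38 genes of the unfolded protein and ATF4 response were shifted down, with a median of -0.14 and 30 below 0 (camera adjusted p = 6.91e-04). Among them ASNS, the asparagine synthetase, stood at -0.81, the chaperone PDIA6 at -0.45 and MANF at -0.42, and adjusted over the list alone 1 rose and 1 fell. The 33 genes of cholesterol synthesis and SREBP targets had a median of -0.18 with 29 below 0 (camera adjusted p = 0.00741), with SCD at -0.53 and INSIG1 at -0.49. Their median was 0.06 at 24 h, higher than 94.2% of random lists of the same size and expression, and -0.40 at 48 h. The 24 measured NRF2 targets had a median of 0.11 with 17 above 0 (camera adjusted p = 0.0118), with HMOX1 at 0.31 and FTL at 0.29. With an estimated correlation none of these 6 calls held (adjusted p = 0.834 for each), and fry, which tests each list by itself, called 0 lists, with 2 at an unadjusted p under 0.05. The estimated-correlation test has 2 residual degrees of freedom and little power. The oxidative phosphorylation list had an estimated correlation of -0.002, under the preset 0.01, and lost its call all the same (unadjusted camera p = 0.037). The ribosomal proteins had an estimated correlation of 0.53, well above the preset.

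The nuclear receptors and their coregulators, the subject of the series title, did not move as groups after siNCOA3. The 23 measured nuclear receptors had a median of -0.002 and the 47 coregulators a median of 0.009, and camera gave adjusted p = 0.774 and 0.439. The median of the nuclear receptors and the direction of the test differed in sign. The list of coregulators leaves out NCOA3, the target. None of the listed nuclear receptors and coregulators was called among all genes or when adjusted over the list alone. ESRRA had a value of 0.34, NR2F2 0.28 and RARA 0.25, and CITED2 had 0.33, PPRC1 0.32 and DDX17 -0.32. Among the 27 ERK output genes PHLDA1 fell, with HBEGF at -0.48 not passing over all genes, and 2 members fell when adjusted over the list alone (camera adjusted p = 0.509 for the list).

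**Figure D2:**
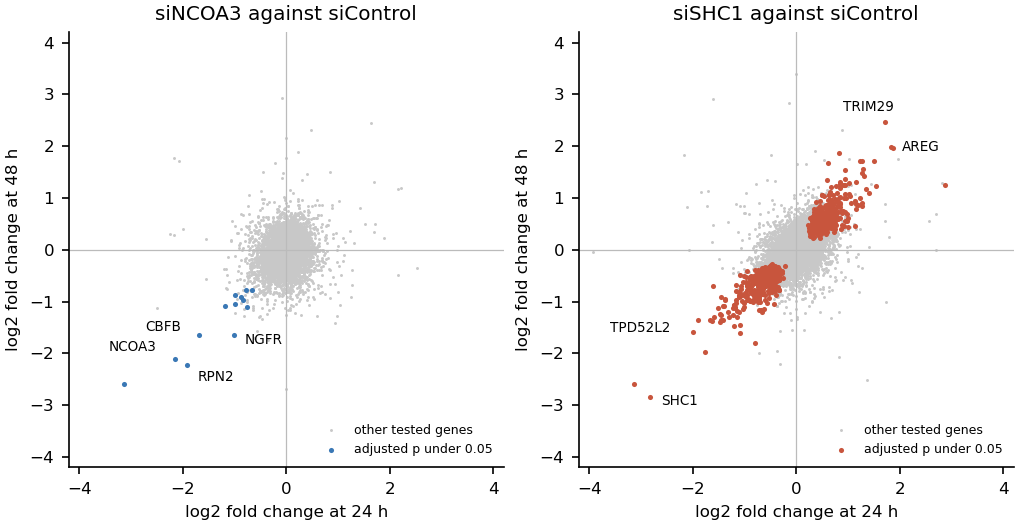
Log2 fold change at 24 h (horizontal axis) and 48 h (vertical axis) of each of the 11690 tested genes after siNCOA3 (left) and siSHC1 (right), against the siControl library of the same time. Coloured points are genes called in the fit over both times, all 13 of them lower after siNCOA3, and 363 higher and 388 lower after siSHC1.

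The comparison of siSHC1 with siControl asks which transcripts depend on SHC1. Among genes with a mean of at least 5 FPKM, the largest rises included AREG (amphiregulin), a ligand of the EGF receptor, which went from 23.8 to 93.0 FPKM at 24 h and from 33.5 to 134 FPKM at 48 h, a rise of 1.91 ± 0.13 on the log2 scale (SE, n = 2 libraries per siRNA, limma adjusted p = 0.00191). AREGB, a near-identical copy of AREG whose reads are hard to tell apart from it, rose by 1.92 ± 0.12. TRIM29, a protein of basal epithelia, rose by 2.09 ± 0.18, from 3.90 to 25.9 FPKM at 48 h (limma adjusted p = 0.00384). The water channel AQP3 rose by 1.49 ± 0.14, the hypoxia-induced carbonic anhydrase CA9 by 1.42 ± 0.23, GDPD5 by 1.38 ± 0.12, gamma-synuclein (SNCG) by 1.37 ± 0.14, the chemoattractant RARRES2 by 1.24 ± 0.15, the neurotrophic ligand ARTN by 1.24 ± 0.15 and the lipid transporter ABCA7 by 1.16 ± 0.25.

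The integrin beta-1 subunit, ITGB1, fell by 1.38 ± 0.06 after siSHC1, from 445 to 179 FPKM at 24 h and from 481 to 184 FPKM at 48 h (limma adjusted p = 0.000552). TPD52L2 fell by 1.79 ± 0.11 and ATP6V0C, a membrane subunit of the vacuolar proton pump, fell by 1.63 ± 0.14. SRPR, the receptor of the signal recognition particle, was 2.83-fold lower and ADI1, an enzyme of methionine salvage, 2.82-fold lower in the fit. The changes of SH3GLB1 (-1.45 ± 0.10), SPAG7 (-1.44 ± 0.11), TMEM164 (-1.41 ± 0.10) and the chromatin protein MORF4L1 (-1.36 ± 0.08) completed the largest falls among genes with a mean of at least 5 FPKM. In all 751 genes changed (limma adjusted p under 0.05), 363 higher and 388 lower, with 77 changed by 2-fold or more, 35 higher and 42 lower. All 751 moved the same way at both times, which the fit asks of a call and which is therefore no separate result. Without a test 58 genes changed 2-fold the same way at both times, 24 higher and 34 lower. The count became 59 without the siControl library of 24 h, 110 without that of 48 h, 245 and 422 without the siSHC1 library of 48 h and 24 h, 226 without the term for time and 2 without a filter on low values, and with equal library totals 705 genes were called, 209 higher and 496 lower (limma). The word GCCCATC, which occurs in the SHC1 transcript outside its 3′ UTR, lies in the 3′ UTR of 156 of the 380 genes that fell, other than SHC1 and with a 3′ UTR, or 41.1%, against 5.35% of those that rose and 6.73% of genes not called, and among the 10 genes named here as the largest falls, SHC1 included, SRPR and SHC1 lack it. This word too was chosen by these same fold changes, which favours its share among the falls.

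Genes of hypoxia and glycolysis were shifted up as a list by camera after siSHC1, though not with an estimated correlation. Of 33 measured members 17 rose and 2 fell, and 24 rose and 3 fell when adjusted over the list alone. Their median was 0.41, with 29 members above 0 (camera adjusted p = 6.28e-10, and adjusted p = 0.746 with an estimated correlation). Enolase 2 (ENO2) rose by 1.09 ± 0.13, the prolyl hydroxylase EGLN3 by 1.04 ± 0.20, and ALDOC at 1.15 did not pass (limma adjusted p = 0.0636). The pyruvate kinase PKM (-1.25 ± 0.11) and the hexokinase HK1 (-0.68 ± 0.09) fell, and both carry GCCCATC in their 3′ UTR.

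The lists of cell cycle genes were shifted down by camera after siSHC1, and these calls too were lost with an estimated correlation and with fry. Of 47 genes of G2/M and mitosis 4 fell and 0 rose by limma, 11 fell when adjusted over the list alone, and 39 lay below 0, with a median of -0.16 (camera adjusted p = 7.58e-07, and adjusted p = 0.746 with an estimated correlation). The mitotic transcription factor FOXM1 (-1.15 ± 0.08), the phosphatase CDC25B (-1.13 ± 0.08) and the spindle midzone protein PRC1 (-0.81 ± 0.11) fell, and CENPA at -0.41 did not pass. CDC25B and PRC1 carry GCCCATC in their 3′ UTR and FOXM1 does not. Of 45 genes of G1/S and DNA replication 6 fell, 12 fell when adjusted over the list alone, and the median was -0.17 with 36 below 0 (camera adjusted p = 2.98e-05, and adjusted p = 0.746 with an estimated correlation). CDCA7 (-0.84), the uracil glycosylase UNG (-0.63), GINS4 (-0.57) and the ligase LIG1 (-0.55) fell, and GINS4 carries GCCCATC in its 3′ UTR.

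Epithelial genes were shifted up as a list by camera after siSHC1, a call lost with an estimated correlation and with fry. Of 19 measured members 5 rose, 12 rose and 1 fell when adjusted over the list alone, and the median was 0.36 with 16 above 0 (camera adjusted p = 1.18e-05, and adjusted p = 0.746 with an estimated correlation). Claudin 4 (CLDN4) rose by 0.73 ± 0.08 and keratin 19 (KRT19) by 0.64 ± 0.09, and SPINT1 at 0.79 did not pass. The 10 measured markers of luminal breast cells, a list that shares KRT19 with the epithelial one, had a median of 0.26 with 9 above 0, and KRT19 and AGR2 rose (camera adjusted p = 0.0134, and adjusted p = 0.746 with an estimated correlation). The 33 genes of cholesterol synthesis and SREBP targets had a median of 0.33 with 31 above 0 (camera adjusted p = 7.39e-06, and adjusted p = 0.746 with an estimated correlation). EBP rose by 0.50, 3 members rose when adjusted over the list alone, and INSIG1 at 1.10 ± 0.30, MSMO1 at 0.90 ± 0.20, SCD at 0.70 and HMGCS1 at 0.70 did not pass over all genes.

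The camera calls were completed by 4 further lists. Of the 25 measured NF-kB and cytokine genes, NFKB1 fell by 0.58 ± 0.09, and IL8 and CXCL1 fell at a low level. The median was -0.17 with 19 below 0, at 0.03 at 24 h and -0.25 at 48 h (camera adjusted p = 0.0297). The 24 NRF2 targets had a median of 0.11 with 23 above 0, the 13 measured mitochondrially encoded transcripts a median of 0.095 with 12 above 0 (camera adjusted p = 0.0126 for both), and the 40 genes of oxidative phosphorylation a median of 0.090 with 31 above 0 (camera adjusted p = 0.0212). Among these COX7A2 rose, and FTH1 at 0.34 and MT-CO2 at 0.20 did not pass. With an estimated correlation the adjusted p of each of these 4 lists was 0.746. The NF-kB, NRF2 and oxidative phosphorylation lists were called in the same directions after siNCOA3, against the same siControl libraries. Between siSHC1 and siNCOA3 they were not called (camera adjusted p = 0.503, 0.820 and 0.931). A shift in the siControl libraries therefore cannot be told apart from an effect of both siRNAs. Over all 28 lists fry called 0, with 5 at an unadjusted p under 0.05, while its test for change in either direction called 22.

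Members of the signalling lists around SHC1 moved both ways, and these lists did not move as groups. Among 40 genes of the receptor tyrosine kinase and RAS-MAPK pathway the EGF receptor (EGFR, -0.62) and RASA1 (-0.42) fell, and RRAS rose by 0.61 (camera adjusted p = 0.403 for the list). Adjusted over the list alone 2 rose and 4 fell. Among 27 ERK output genes AREG, EREG (by 1.04 ± 0.13), HBEGF (by 0.61) and IER3 (by 0.34) rose and the survival gene MCL1, which carries GCCCATC in its 3′ UTR, fell by 1.10 ± 0.09 (camera adjusted p = 0.356 for the list). Adjusted over the list alone 6 rose and 4 fell. Among 36 genes of invasion, adhesion and matrix proteases ITGB1, the focal adhesion adaptor PXN (-0.79 ± 0.07) and the membrane protease MMP14 (-0.57) fell, and ITGA5 (by 0.88 ± 0.10), ADAM19 (by 0.69), LOXL2 and CTSD rose (camera adjusted p = 0.687 for the list). Adjusted over the list alone 7 rose and 5 fell. Of the 23 nuclear receptors RARA rose by 0.41, and of the 47 coregulators CTBP1, which carries GCCCATC, fell by 0.44 (camera adjusted p = 0.976 and 0.720). Adjusted over the list alone, 0 nuclear receptors and 0 coregulators passed by limma.

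**Figure D3:**
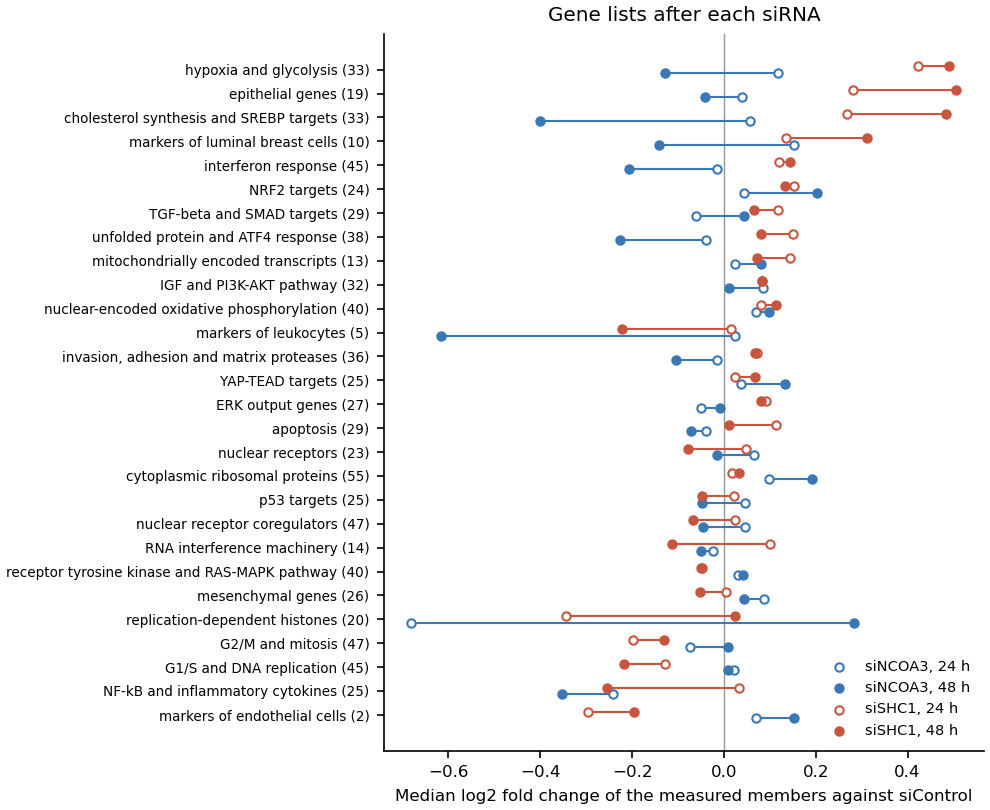
Median log2 fold change against siControl of the measured members of each of the 28 gene lists (number of members in parentheses), at 24 h (open circles) and 48 h (filled circles), after siNCOA3 (blue) and siSHC1 (red). After siSHC1 hypoxia and glycolysis stands at 0.42 and 0.49 and the cell cycle lists stand below 0 at both times, and after siNCOA3 the histones stand at -0.68 at 24 h and 0.28 at 48 h.

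The direct comparison of siSHC1 with siNCOA3 tests where the knockdowns differed, without the siControl libraries entering the difference. RPN2 was higher after siSHC1 by 2.36 ± 0.09 on the log2 scale (SE, n = 2 libraries per siRNA, limma adjusted p = 2.43e-04), NCOA3 by 2.29 ± 0.10, AREGB by 2.06 ± 0.12, AREG by 2.05 ± 0.13 and NGFR by 1.78 ± 0.15. SHC1 was lower, at -2.74 ± 0.08 (limma adjusted p = 6.28e-05), as were ATP6V0C at -1.86 ± 0.14, TPD52L2 at -1.83 ± 0.11, the amino acid transporter SLC7A5 at -1.73 ± 0.09 and ADI1 at -1.67 ± 0.10. In all 1139 genes differed, 625 higher and 514 lower after siSHC1, and 114 differed by 2-fold or more, 70 higher and 44 lower. The count was 178 and 671 without the siNCOA3 library of 48 h and 24 h, 355 and 708 without that of siSHC1, 450 without the term for time and 4 without a filter on low values, and with equal library totals 1156 genes differed, 510 higher and 646 lower (limma).

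Of the 28 lists 8 differed between the knockdowns by camera, and 0 with an estimated correlation or with fry, which had 0 and 4 at an unadjusted p under 0.05. Hypoxia and glycolysis was higher after siSHC1, with a median of 0.49, 20 members higher and 2 lower, and 25 and 2 when adjusted over the list alone (camera adjusted p = 1.13e-08). Cholesterol synthesis was higher, with a median of 0.49, 5 members higher, and 16 when adjusted over the list alone (camera adjusted p = 1.26e-08). Among these HMGCS1 differed by 1.10 and MSMO1 by 1.02. The unfolded protein and ATF4 response had a median of 0.23, with 8 members higher, among them MANF by 0.69 and PDIA6 by 0.62, and 2 lower, SLC7A5 and its partner SLC3A2 (camera adjusted p = 0.00165). The epithelial list stood at 0.36 with 6 members higher (camera adjusted p = 1.97e-04), and the interferon response at 0.17, with IFIT2, ISG20 and TAP1 higher (camera adjusted p = 0.00359). Ribosomal proteins stood at -0.12 with 3 lower (camera adjusted p = 1.41e-07), G2/M and mitosis at -0.14 with 7 lower (camera adjusted p = 5.47e-05), and G1/S and DNA replication at -0.15 with 10 lower (camera adjusted p = 1.72e-04). With an estimated correlation the adjusted p of each of these 8 lists was 0.767.

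Genes that fell after both siRNAs numbered 2, CBFB and LSP1, where independent lists of 13 and 388 among 11690 genes would share 0.431, and part of the excess may come from the shared siControl libraries. CBFB fell by 1.26 after siSHC1 (limma adjusted p = 0.00522) and carries both words in its 3′ UTR. Across genes, which are not independent replicates, 9 pairs of fold changes were correlated. The changes of siSHC1 at 24 h and 48 h, which share no library, correlated at Pearson r = 0.544 (Spearman rho = 0.544), and those of siNCOA3 at r = 0.198 (rho = 0.184). The changes of siNCOA3 and siSHC1 correlated at r = 0.379 at 24 h and 0.223 at 48 h, where they share a control and unchanged libraries simulated against that control gave 0.497. Their covariance was 0.0283 and 0.0204, against 0.0179 in the simulation. Without a shared library r was 0.105 between siNCOA3 at 24 h and siSHC1 at 48 h and -0.083 between siNCOA3 at 48 h and siSHC1 at 24 h. The changes from 24 h to 48 h, which share no library either, correlated at r = 0.390 between siControl and siSHC1. They correlated at 0.168 between siControl and siNCOA3 and at 0.160 between siNCOA3 and siSHC1.

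The comparison of 48 h with 24 h asks what changed with time after transfection in all siRNAs. Time and collection are the same here, so hours since transfection cannot be told apart from any other difference between the collections. ZSCAN18, a zinc finger protein, rose by 1.25 ± 0.10 on the log2 scale (SE, n = 3 libraries per time, limma adjusted p = 0.0235), from 19.8 to 62.9 FPKM with siControl, 21.4 to 48.8 with siNCOA3 and 19.0 to 39.8 with siSHC1. The other called genes, named after their values were seen, were AL050302.1, which was listed at 0 in the 3 libraries of 24 h and at 7.92, 13.1 and 5.67 FPKM at 48 h, and RP11-680G10.1, which fell from 1.62, 4.06 and 2.10 FPKM to 0, 0.824 and 0. In all 3 genes changed, 2 higher and 1 lower, and 1660 had an unadjusted p under 0.05. Calls in simulated unchanged libraries were counted for the siRNA comparisons alone, with up to 10 for siNCOA3 and 11 for siSHC1. The number 3 by itself therefore does not show a change with time. TRIM29 (2.30-fold), R3HDM2 at 0.71, BBS1 at 0.70 and TSC22D3, a glucocorticoid-induced gene, at 0.66 were higher at 48 h with every siRNA and did not pass. AP002348.1 at -4.69, LUZP6 at -1.68, GLMN at -0.55, the cyclin CCNE2 at -0.48 and AKTIP at -0.45 were lower with every siRNA and did not pass. The count was 0 without the siControl library of 24 h or that of 48 h, where 870 and 871 genes had an unadjusted p under 0.05, 46 and 44 without the siNCOA3 library of 24 h and 48 h, 9 without either siSHC1 library, and 0 without a filter on low values, where 1698 genes had an unadjusted p under 0.05 (limma).

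All 45 genes of G1/S and DNA replication were lower at 48 h, with a median of -0.22 (camera adjusted p = 7.02e-20, and adjusted p = 0.783 with an estimated correlation; fry adjusted p = 0.502), and 21 fell when adjusted over the list alone, with DSCC1 at -0.47, RFC3 at -0.43 and CLSPN at -0.37. The 33 genes of cholesterol synthesis had a median of 0.44 with 32 above 0 (camera adjusted p = 7.83e-15), and 17 rose when adjusted over the list alone, with SCD at 0.98, INSIG1 at 0.95 and TM7SF2 at 0.71. Their median was 0.51 with siControl, 0.05 with siNCOA3 and 0.79 with siSHC1. Hypoxia and glycolysis stood at 0.20 (camera adjusted p = 6.67e-09), the epithelial list at 0.23 with 19 of 19 above 0 (camera adjusted p = 4.79e-07), the interferon response at 0.13 (camera adjusted p = 8.10e-05), the luminal markers at 0.18 with 10 of 10 above 0 and the ribosomal proteins at -0.04 (camera adjusted p = 0.00245 for both). G2/M and mitosis stood at -0.08 (camera adjusted p = 0.00341), the histones at -0.20 (camera adjusted p = 0.00388) and NF-kB and cytokines at 0.13 (camera adjusted p = 0.0158). With siControl, siNCOA3 and siSHC1 in turn the medians were 0.21, 0.02 and 0.35 for hypoxia and glycolysis and 0.20, 0.03 and 0.24 for the interferon response, with little shift after siNCOA3. They were 0.26, 0.23 and -0.08 for NF-kB and cytokines, -0.54, 0.27 and -0.18 for the histones and -0.07, 0.009 and -0.06 for the ribosomal proteins, so that 1 siRNA went the other way in each. With an estimated correlation none of these 10 calls held. The adjusted p was then 0.783 for G1/S, cholesterol, hypoxia, epithelial, interferon, luminal and G2/M genes, 0.808 for histones and NF-kB and 0.890 for ribosomal proteins. No single member of a list changed with time over all genes tested by limma.

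The 7-base words that go with falling genes were sought in the 3′ UTRs of 11276 genes. Genes with GCCCATC in the 3′ UTR, 884 in number, had a mean log2 change of -0.19 after siSHC1, and genes without it had 0.02. The mean was -0.17 with the word once, -0.29 with 2 or more copies, and -0.06 with the word outside the 3′ UTR alone. It hardly differed between 3′ UTRs where an A follows the word (-0.19) and those where none does (-0.18). Genes with GTCAAGA in the 3′ UTR, 907 in number, had a mean of -0.08 after siNCOA3, and genes without it had -0.005. The mean was -0.08 with this word once, -0.09 with 2 or more copies (medians -0.06 and -0.04), and -0.04 with the word outside the 3′ UTR alone. With a following A it was -0.14, and without one -0.05.

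**Figure D4:**
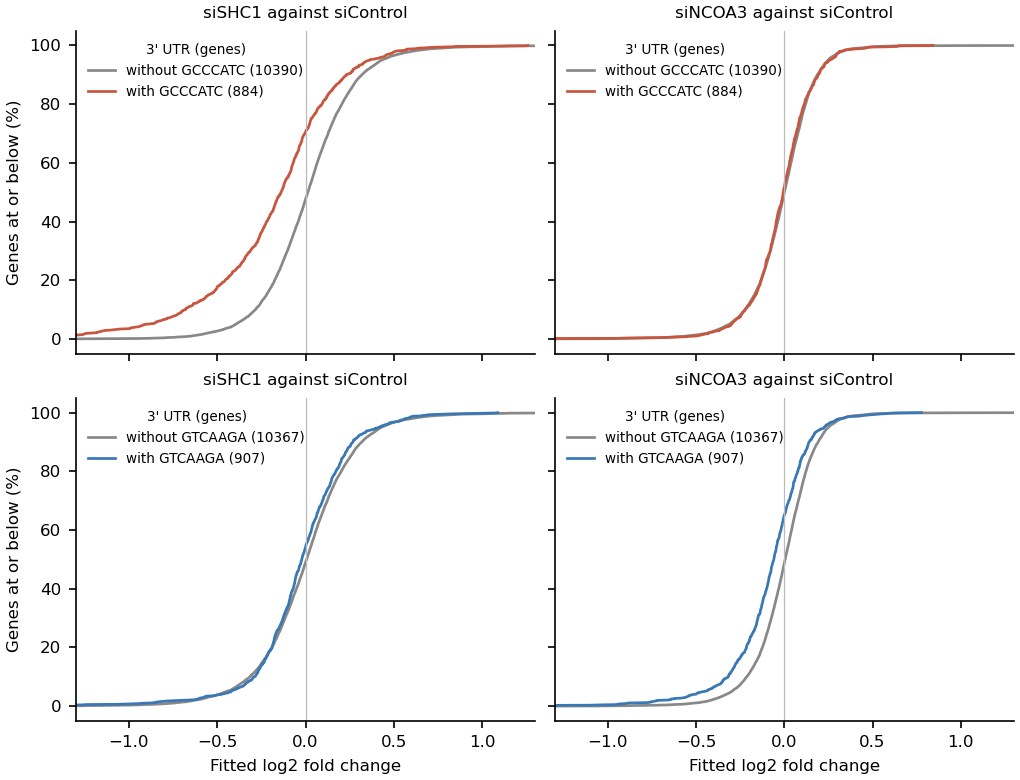
Cumulative share of genes at or below each fitted log2 fold change, for genes with a word in the 3′ UTR (coloured) and without it (grey), with GCCCATC in the upper panels and GTCAAGA in the lower ones, after siSHC1 (left) and siNCOA3 (right). Genes with GCCCATC lie lower after siSHC1 (mean -0.19 against 0.02) and genes with GTCAAGA lie lower after siNCOA3 (mean -0.08 against -0.005), and in the other pair of panels the curves lie close together.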

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

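In this part the tests of the siSHC1 depth by the correlation across times, of the siNCOA3 fold changes after removal of the GC and length trend, of genes without the words, and of other splits of the libraries were chosen after the results were seen. The other tests were fixed beforehand.

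Some gene lists moved in opposite directions at the times or under the siRNAs, each median lying in an outer tail of 10000 random lists of the same size and expression; these differences were not tested. Hypoxia and glycolysis genes stood at 0.12 after siNCOA3 at 24 h and at -0.13 at 48 h. Replication-dependent histone genes stood at -0.68 after siNCOA3 at 24 h and at 0.28 at 48 h. After siSHC1, against the same siControl libraries, they stood at -0.34 at 24 h, also in an outer tail, and at 0.02 at 48 h, which was not. From 24 h to 48 h the histones moved by -0.54 with siControl, 0.27 with siNCOA3 and -0.18 with siSHC1. These time values come from the same libraries as the values against siControl, so they are no separate observation. A shift particular to the single siControl library of 24 h is not excluded. From 24 h to 48 h genes of the unfolded protein and ATF4 response moved by 0.19 with siControl and -0.035 with siNCOA3.

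The genes that fell after siNCOA3 include 6 of 12, NCOA3 aside, with GTCAAGA in the 3′ UTR, and of all 7-base words this one went most with falling genes (z = -11.5, against an extreme of -4.95 in 100 permutations, none of which was as low). The word occurs in the NCOA3 transcript, as do 34.1% of the 16139 words tested, so a hypothesis is that RPN2, CBFB and other carriers may have fallen through seed pairing of the siRNA. An effect of 3′ UTR base composition shared by both knockdowns is argued against, because the same word had a z of -0.317 after siSHC1. That value cannot exclude a composition trend particular to the siNCOA3 libraries. For GC content and length the test fixed beforehand does not decide: after the trend was removed 10 of 13 genes (76.9%) were still called, under the 80% set for excluding it, and the lost ones were CSF1 (-0.93 ± 0.10 before, -0.92 after, limma adjusted p from 0.0467 to 0.0505), FERMT2 (-0.93 to -0.91, adjusted p 0.0492 to 0.0610) and NGFR (-1.33 to -1.32, adjusted p 0.0492 to 0.0610), which had stood next to the threshold and whose SEs hardly moved. The size of the falls argues against that trend as their source, since the median over the 13 genes went from -1.02 to -1.01 and no gene moved by more than 0.023. Loss of NCOA3 itself stays open for NGFR, F2RL1, RRBP1, FERMT2 and BCL2L1, which lack GTCAAGA in the 3′ UTR. It stays open less plainly for LSP1, which was listed at 0 after siSHC1 too, where NCOA3 stood at 115% and 111% of siControl. Another effect of the siRNA is not excluded for these genes, as other words were not looked up in them. The word GAATTGA, also in the NCOA3 transcript, had a z of -6.39 and lay in 5 of the 12 genes, against 11.2% of all genes.

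The genes that fell after siSHC1 carry GCCCATC in the 3′ UTR far more often than other genes, in 31 of 40 (77.5%) of those that fell 2-fold or more against 6.73% of genes not called, and the word had the lowest z of all words (-19.4, and -18.4 and -16.2 at 24 h and 48 h alone, against an extreme of -4.77 in 100 permutations). As the word was chosen by these fold changes, its shares among the falls are not independent support. The word lies in the SHC1 transcript, as do 18.4% of the words tested, so seed pairing of the siRNA is a candidate explanation for the fall of ITGB1, PKM, MCL1, CDC25B and other carriers. A base composition effect shared by both knockdowns is argued against by a z of 0.754 for the same word after siNCOA3. That value cannot exclude a composition trend particular to the siSHC1 libraries. The word TTTTAAA also went with falling genes there (z = -7.02, with 0 of 100 permutations as low). An equal effect from outside the 3′ UTR is argued against by means that differ by 0.129 ± 0.015 (SE). Without the carriers 576 of the 751 genes were still tested and 333 were called, 190 higher and 143 lower, and camera called its 10 lists again, calls that in the full set are lost with an estimated correlation and with fry. The rest of the 576 lack the word and lost the call in this refit with their fold changes unaltered. The drop to 333 therefore does not measure the part owed to carriers. FOXM1, EGFR and PXN fell and lack the word in the 3′ UTR. Their falls may follow from the loss of SHC1, from the fall of a carrier or from another effect of the siRNA. These data cannot separate such sources. Genes with the word outside the 3′ UTR alone had a mean of -0.06, against 0.03 with no word.

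The number of genes changed by siSHC1, 751 against 13 by siNCOA3, was weighed against technical sources. After the trend of each library with GC content and length was removed, 612 of the 751 (81.5%) were still called in the same direction, just past the 80% set beforehand for excluding it as the source of the number. The calls were then 281 higher and 372 lower, against 363 and 388 before. The 80% was therefore passed by the pooled number, while the rises taken alone fell short of it. The siSHC1 libraries were among the shallowest, and the test of depth fixed beforehand gave at most 16 calls in 20 simulated sets of unchanged libraries with depth noise. As that rests on an assumed transcript length of 2 kb, the correlation across the times was added: r = 0.544 over libraries that share nothing, where counting noise alone would give a value near 0. A biological response to SHC1 loss and an effect of the siRNA on other transcripts both stay open, as a second siRNA against SHC1 was not analysed here.

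Of the 10 splits of the 6 libraries into 3 and 3, only 1, the split by time, gave as many as 3 genes, and the highest other split gave 1. With 10 splits the share cannot fall under 0.1, so the design is too small for this test to reach the threshold. Splits with 1 library of each siRNA on each side, the like of the split by time, are fewer still, and the highest other split was among them. The remaining splits put both libraries of an siRNA on the same side and so also hold differences between siRNAs.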

How the results depend on the processing

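The settings without scaling, with a mean of at least 5 FPKM for the tests, with pseudocount 0.1, with the GC and length trend removed and without word carriers were chosen after seeing the data; pseudocounts of 0.5 and 5 had been planned for counts. The planned count normalizations, the DESeq2 and voom tests and the binomial intervals need counts and were not run. For the targets and the genes named by the size of their change, 932 values were computed under the other scalings, filters, pseudocounts, models and sets of libraries, but not with the GC and length trend or the word carriers removed. Of these 0 changed sign, 821 kept their side of the threshold, 106 lost the call and 5 gained it. Apart from the targets, the genes had been named for large changes of the same sign in every pair of libraries. A change of sign was therefore unlikely from the start. The 821 include genes that were named without a call. No named siNCOA3 gene and 2 of 20 named siSHC1 genes passed under every scaling, filter, pseudocount and model. Between siSHC1 and siNCOA3 3 of 10 did so, and for time ZSCAN18 did not.

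Without a filter on low values limma called 0 genes for siNCOA3 (1375 at an unadjusted p under 0.05), 2 for siSHC1 (3310), 4 for siSHC1 with siNCOA3 (3693) and 0 for time (1698), with 16511 genes tested and a median prior degrees of freedom of 2.14 in place of 4.85. Without the term for time siSHC1 had 226 genes and siSHC1 with siNCOA3 450, and without that for siRNA time had 1. Without scaling siNCOA3 had 7 genes, and SHC1 after siSHC1 stood at 13.7% of siControl, and at 12.8% with equal totals, against 13.3%. With equal totals siSHC1 had 209 higher and 496 lower genes against 363 and 388, and siSHC1 with siNCOA3 had 510 and 646 against 625 and 514. The libraries of siControl and siNCOA3 alone gave 29 genes for siNCOA3, 12 of them among the 13, and 9 for time, those of siControl and siSHC1 gave 49 for time, and those of siNCOA3 and siSHC1 gave 0 for time (870 at an unadjusted p under 0.05). Time had 1 gene with a mean of at least 5 FPKM. It also had 1 with pseudocount 5, which was not among the 3 called in full. Without word carriers siNCOA3 had 5 genes and siSHC1 333. The causes of these shifts were not tested, apart from the fewer genes or libraries that a setting holds.

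Leaving out each library in turn gave 3 to 30 genes for siNCOA3, 59 to 758 for siSHC1, 178 to 956 for siSHC1 with siNCOA3 and 0 to 46 for time. Of the 751 siSHC1 genes 57 were called again without siControl at 24 h (59 in all), 95 without siControl at 48 h (110), 209 without siSHC1 at 48 h (245) and 314 without siSHC1 at 24 h (422). Lists called by camera numbered 4 to 10 for siNCOA3 (6 in full), 7 to 11 for siSHC1 (10), 8 to 10 for siSHC1 with siNCOA3 (8) and 6 to 11 for time (10, and 6 without either siControl library). With an estimated correlation, and with fry, each comparison had 0 lists. The lists at an unadjusted p under 0.05 by fry were 2, 5, 4 and 2, and with an estimated correlation 1, 0, 0 and 0. Every list called by camera kept the sign of its median under both other scalings.

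Genes changed 2-fold at both times by siNCOA3 were 11, and 32, 20 and 4 with pseudocounts of 0.1, 0.5 and 5, 7 with a mean of at least 5 FPKM, 64 at 1.5-fold and 5 at 3-fold. For siSHC1 they were 58, and 117 and 21 with pseudocounts of 0.1 and 5, 316 at 1.5-fold and 8 at 3-fold. With a mean of at least 20 FPKM the correlation of the times was 0.361 for siNCOA3 and 0.699 for siSHC1. With 1 library per siRNA and time, depth and replication limit what can be said of single times.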

Other observations

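The hypothesis tests named in the preceding parts are not repeated, and the values here come from lists fixed beforehand with no test chosen later. Among genes of the unfolded protein and ATF4 response, siSHC1 lowered the amino acid transporter pair SLC7A5 (-1.26 ± 0.09) and SLC3A2 (-0.74 ± 0.13) and raised VLDLR (0.74 ± 0.11) and the chaperone CALR (0.41 ± 0.08), and the list as a whole did not move (camera adjusted p = 0.240). SLC7A5 carries GCCCATC in its 3′ UTR. Adjusted over the list alone 3 rose and 2 fell. Of 26 mesenchymal genes the collagens COL5A1 (0.74 ± 0.09) and COL1A1 rose after siSHC1, the latter with 2 copies of GCCCATC in its 3′ UTR, 5 rose and 7 fell when adjusted over the list alone, and SNAI2 at -0.44, ZEB1 at -0.43 and S100A4 at 0.44 did not pass over all genes (camera adjusted p = 0.755). Of 29 TGF-beta and SMAD targets the latent TGF-beta binding protein LTBP3 (1.02 ± 0.13), BHLHE40 (0.57 ± 0.09) and COL1A1 rose and PMEPA1 (-0.48 ± 0.10) fell, and ANGPTL4 at 1.38 did not pass (camera adjusted p = 0.160). Adjusted over the list alone 4 rose and 1 fell. Of 25 YAP-TEAD targets tissue factor (F3, 0.94 ± 0.14) rose and CCDC80 (-0.66 ± 0.10) fell (camera adjusted p = 0.899), and 1 and 2 did so when adjusted over the list alone.

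Of 25 p53 targets PMAIP1 (0.62 ± 0.11) and CDKN1A (0.47 ± 0.11) rose after siSHC1, over all genes and when adjusted over the list alone (camera adjusted p = 0.755). Of 29 apoptosis genes MCL1 and CASP10 fell, 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.763), and after siNCOA3 BCL2L1 fell and TNFSF10 at -0.88 did not pass over all genes. Of 32 genes of the IGF and PI3K-AKT pathway PDK1 (0.48 ± 0.10, with GCCCATC in its 3′ UTR), IRS1 (0.40 ± 0.09) and IGFBP4 (0.31 ± 0.06) rose after siSHC1, with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.219). Of 45 interferon genes ISG20 rose after siSHC1 and IFIT2 at 0.70, ISG15 at 0.55, IFIT3 at 0.53 and GBP1 at -0.53 did not pass, and 0 passed by limma when adjusted over the list alone (camera adjusted p = 0.0515). Of 55 ribosomal protein genes RPS16, which carries GCCCATC, fell after siSHC1 (-0.71 ± 0.06), and the list did not move (camera adjusted p = 0.720). In the 14 measured genes of the RNA interference machinery none was called after either siRNA by limma over all genes, 1 was lower when adjusted over the list alone after each, and the medians were 0.014 after siNCOA3 and -0.033 after siSHC1 (camera adjusted p = 0.929 and 0.899). Of the 20 measured histone genes none was called after either siRNA (camera adjusted p = 0.0786 and 0.120). Of the markers of other cell types, 5 of 16 for leukocytes and 2 of 10 for endothelial cells were measured, and none was called over all genes after either siRNA, with camera adjusted p from 0.277 to 0.899. Adjusted over the list alone, 1 leukocyte marker was lower after siNCOA3, and 1 was higher and 2 were lower after siSHC1.

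Over all 28 lists, those that camera did not call had adjusted p from 0.0786 to 0.929 after siNCOA3, from 0.0515 to 0.976 after siSHC1, from 0.0933 to 0.969 between the siRNAs and from 0.101 to 0.879 between the times. A principal component analysis put the siSHC1 libraries at 12.5 and 27.1 on the first component, which held 48.0% of the variance, and the siControl libraries at -14.5 and -0.69 and the siNCOA3 libraries at -13.5 and -10.8.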
